A study of Mus musculus and Homo sapiens with 21 samples.

How the data were processed

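Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in 21 libraries, 18 of mouse and 3 of human cell lines. They fall into 17 groups by target, cell line and treatment, of which 4 hold 2 libraries and 13 hold a single library. The submitters call 1 library of each pair a replicate without saying whether it came from a separate culture, so p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, chromatin had an average fragment size of 500 bp, libraries were amplified over 18 cycles, and fragments of 150 to 300 bp were isolated, which holds shear fragments of 50 to 200 bp.

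The deposited values are lists of aligned read positions, with the sign of each position giving the strand. Per the file headers, the authors aligned the reads with Bowtie to mm8 (mouse) or hg18 (human) and listed separately the reads with a single alignment and those with more. The version of Bowtie is not given in the sources used here. The seed length was 26 bases for the V6.5 libraries, 32 for the human input and 36 for the rest, per the file headers. No region list, count or normalized level was taken from the authors. Annotation of mm8 or hg18 was not used here, so regions are given by coordinates (counted from 1) and no gene is named from them. Gene lists set before the data were examined were therefore not analysed here.

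Reads with a single alignment were used, and at most 1 read per position and strand was kept, which removes copies made during amplification. Each read was moved by 75 bp towards its 3 prime end. Windows of 200 bp in steps of 50 bp were tested with a Poisson p against the highest of 4 means: the genome, the library's own surrounding 10 kb, and the scaled control over 1 kb and 10 kb. Windows at 1e-09 or less were merged when within 200 bp. The control was the IgG library of the same line for C2C12 and 38B9, and whole-cell extract (WCE) for the human cells. Mouse embryonic stem cells (ESC), for which the labels name no control, took the sum of both IgG libraries. For a group with 2 libraries, a region counts when called in both. Overlap means at least 1 shared bp, and was set against 1000 circular shifts of the regions along their chromosomes with a one-sided permutation p, whose smallest possible value is 0.001. Shares carry 95% Wilson intervals, RPM values (reads per region scaled to the distinct reads of the library) carry exact Poisson intervals, and both cover counting error only. A PCR read is not an independent molecule.

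Reads were counted over the union of regions, and library sizes came from a trimmed mean of M values (TMM, trimming 30% of log ratios and 5% of mean levels) over 210554 bins of 10 kb without a region. The tests were planned for count tables. Since the files hold positions, a unit that differs from the one assumed, limma voom took the place of the count test, as set before the data were examined together with the groups, the thresholds, the tests and the rule for named regions. Regions with fewer than 10 reads over the libraries of a fit were left out, and p-values were adjusted by Benjamini-Hochberg at 0.05. A fit of the 6 mouse Smad3 libraries of 3 cell types had 2 residual degrees of freedom, and a fit of the 4 libraries with and without Myod1, with the day as a covariate, had 1. In both, limma estimated no difference in spread between regions beyond its trend with the read count, so every p-value rests on a spread shared by all regions. V6.5 cells after activin and each tetMyod1 group entered these fits with a single library, which is assumed to vary like the others, so their p-values take the spread from the other libraries and cannot part the group from its library. Sets of sites were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation and limma's fry as alternatives. Activin against no activin, and Myod1 against no Myod1 on each day, were compared without a test, as median log2 ratios with a pseudocount of 1 read. For Myod1 at MyoD-Flag regions the median was also set against 10000 random lists of regions matched on read number.

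In each tested comparison the named regions are the 5 in each direction with the smallest adjusted p. In the others they are the 5 with the highest RPM. Named regions lie on numbered chromosomes or X and at least 10 kb from a window called in IgG or WCE. Alternatives were stricter and looser thresholds (1e-12, 1e-07), all deposited reads, calling without the control, thinning, pooled replicates, midpoints within 200 bp, other library sizes, limma trend with a prior count of 2, no filter, other pseudocounts and leaving out each replicate. The comparison with IgG at MyoD and PU.1 sites was added after the data were seen.

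The caller was tested on simulated data: at 0.002 reads per bp it recovered 27% of regions planted at 10-fold and 100% at 30-fold, and at 0.001 reads per bp 2% and 82%, with 0 false regions at either depth. For the simulated comparison of myotubes with pro-B cells (11284 regions), voom recovered 7% of regions changed 4-fold and 35% of those changed 8-fold. For that with and without Myod1 (10621 regions) it recovered 27% and 71%, with 5 false calls. The simulated counts had a dispersion of 0.1 in every library, and the background simulated for the caller was uniform. Real libraries vary more, with 255 and 151 regions called in IgG, so these rates may not carry over. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.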

Results

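Binding of Smad3, a transcription factor that carries TGF-beta and activin signals to the nucleus, was mapped in embryonic, muscle and B-lineage cells, next to a factor characteristic of each cell type. The mouse lines were V6.5 ESC, C2C12 cells differentiated to myotubes for 48 hours, 38B9 pro-B cells and an ESC line with a tetracycline-repressible Myod1 transgene (tetMyod1). The human line was the ESC line BG03 (also spelled BGO3 in the labels). MyoD, which drives the muscle program, was precipitated in myotubes, PU.1, a factor of blood cell development, in pro-B cells, and Oct4, a core pluripotency factor, in BG03. Smad3 was mapped after 2.5 ng/ml TGF-beta for 2 hours in myotubes and after 5 ng/ml for 1 hour in pro-B cells. In V6.5 cells it was mapped with and without 10 ng/ml activin for 1 hour, together with Smad2/3 after activin. PU.1, MyoD, Smad3 in myotubes and Smad3 in pro-B cells had 2 libraries each, and every other group had 1, so comparisons of those groups have no replicate check.

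Depth ranged from 2177352 distinct reads (the second Smad3 library of pro-B cells, in which 19.8% of reads were distinct) to 15561774 (Smad3 on day 2 without Myod1). PU.1 occupied 7160 regions in both of its libraries, out of 7517 and 21757, and reads per region correlated across regions at r = 0.83. MyoD occupied 5005 of 11180 and 7633 regions (r = 0.36). Smad3 in myotubes gave 157 and 868 regions with 64 in both (r = 0.39), and Smad3 in pro-B cells gave 1485 and 256 with 145 in both (r = 0.34). Regions are not independent replicates. IgG gave 255 regions in pro-B cells and 151 in myotubes.

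The first question, raised by the pairing of targets, was whether Smad3 lies where the factor of the cell type lies. In myotubes 47 of 64 Smad3 regions overlapped a MyoD region (73.4%, 95% Wilson interval 61.5 to 82.7%), and in pro-B cells 83 of 145 overlapped a PU.1 region (57.2%, 49.1 to 65%). In BG03 cells 2451 of 3767 Smad3 regions overlapped an Oct4 region (65.1%, 63.5 to 66.6%). The crossed pairs shared far fewer: 2 of 64 myotube regions lay on a PU.1 region of pro-B cells (3.13%, 0.861 to 10.7%) and 10 of 145 pro-B regions on a MyoD region of myotubes (6.90%, 3.79 to 12.2%). Shifted regions overlapped at 0.156% for MyoD, 0.223% for PU.1 and 0.184% for Oct4, with an adjusted permutation p of 0.00125 for each, from the smallest p that the shifts can give. Pro-B regions also exceeded shifted regions on MyoD (adjusted permutation p = 0.00125). Myotube regions did so on PU.1 at 0.011, a call that was lost without the second PU.1 library (adjusted permutation p = 0.135), without regions near IgG or WCE windows (0.135), with midpoints within 200 bp (0.0619) and at 1e-12 (0 of 27 regions). That share was 11.3% (140 of 1235) with pooled replicates, 7.45% (24 of 322) with all deposited reads and 5.30% (8 of 151) at 1e-07, each at adjusted permutation p = 0.001. The myotube share fell to 43.3% (68 of 157) when the second Smad3 library was left out, and libraries thinned to the shallowest left 2 myotube regions, of which 0 overlapped (Wilson upper bound 65.8%), and a pro-B share of 25% (13 of 52). Without the control in the background, 40 of 149 myotube regions lay on PU.1 regions (26.8%) and 50 of 402 pro-B regions on MyoD regions (12.4%).

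Of the 5 myotube regions with the highest mean Smad3 RPM, 3 overlapped a MyoD region, and of the 5 pro-B regions 2 overlapped a PU.1 region. Chromosome 1 136061401–136062100 (mm8) held 3.83 and 13.5 Smad3 RPM (reads scaled to the distinct reads of the library) in the myotube libraries and 78.3 and 23.7 MyoD RPM, against 0.591 for IgG. Chromosome 13 46630551–46631000 held 27 and 55 Smad3 reads, 151 and 114 MyoD reads and 0 IgG reads, and chromosome 11 59139151–59139600 held 19 and 60, 223 and 107, and 1. Outside MyoD regions, chromosome 2 173056901–173057350 held 41 and 54 Smad3 reads, 30 and 15 MyoD reads and 5 IgG reads, and chromosome 15 38415201–38415800 held 31 and 57, 78 and 32, and 3. Chromosome 6 120533001–120533550 held 20.4 and 22.96 Smad3 RPM in pro-B cells, 52.3 and 57.9 of PU.1 and 2.62 of IgG. Chromosome 2 148254801–148255250 held 125 and 55 Smad3 reads, 136 and 258 PU.1 reads and 7 IgG reads. Chromosome 17 29217351–29217950, highest by mean RPM in pro-B cells through the shallow second library, overlapped no PU.1 region, with 7.86 and 43.2 Smad3 RPM (73 and 94 reads), 1.83 and 5.21 of PU.1 and 1.64 of IgG. The other pro-B regions outside PU.1 regions were chromosome 15 63487551–63488100, with 139 and 59 Smad3 reads, 26 and 99 PU.1 reads and 9 IgG reads, in a MyoD region of myotubes, and chromosome 5 114093501–114094000, with 144 and 57, 35 and 64, and 19.

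**Figure D1:**
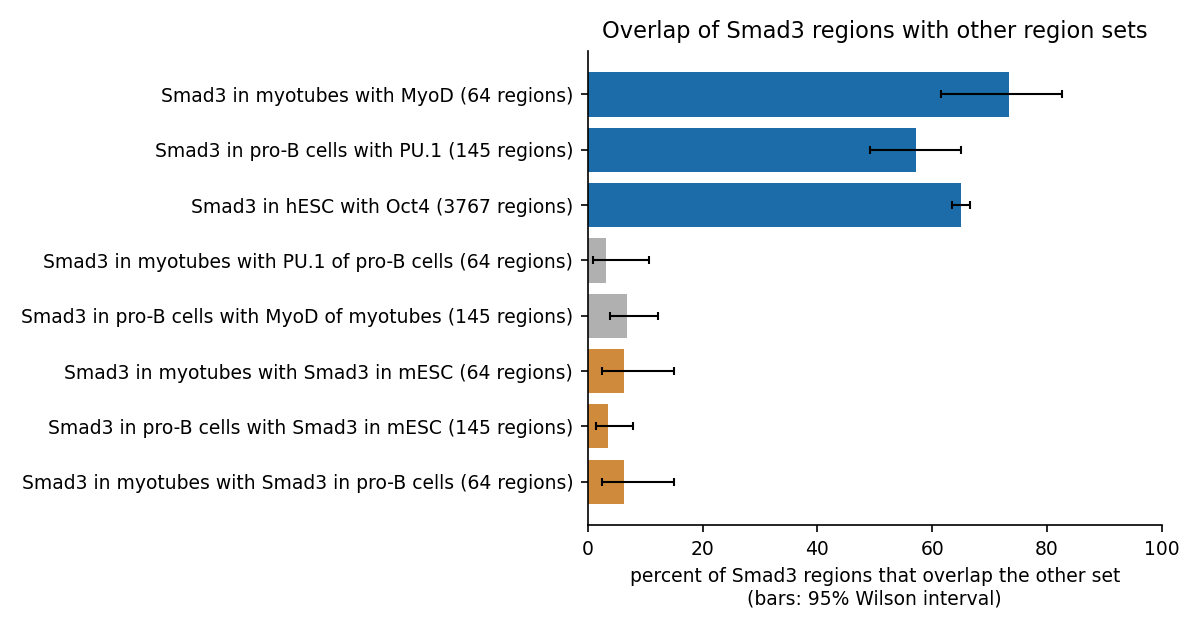
Percent of Smad3 regions (horizontal axis) that overlap another set of regions, with 95% Wilson intervals; blue bars are the factor of the same cell type, grey bars the crossed pairs and orange bars Smad3 regions of another cell type. The blue bars lie between 57.2 and 73.4% and the others at 6.90% or below.

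Smad3 reads followed the cell type also at MyoD and PU.1 sites taken from the other libraries, but at PU.1 sites the IgG reads did the same. Ligand, dose or time of treatment also differed between the cell types, so no comparison of their Smad3 libraries can part cell type from treatment. At 3936 MyoD sites the median log2 fold change of Smad3, myotubes over pro-B cells, was 1.85, with 89.3% of sites higher in myotubes. At 5675 PU.1 sites it was -1.82, with 7.91% higher in myotubes. Over all 7074 PU.1 sites the log2 ratio of summed reads, myotubes over pro-B cells, was -1.96 for Smad3 (95% interval over sites -2.00 to -1.92) and -1.97 for IgG (-2.01 to -1.94), a difference of 0.019 (-0.031 to 0.066). At 4919 MyoD sites it was 1.80 for Smad3 (1.71 to 1.89) and -0.15 for IgG (-0.21 to -0.09), a difference of 1.95 (1.86 to 2.04). Camera gave adjusted p = 4.61e-91 for MyoD sites and 9.43e-87 for PU.1 sites, which became adjusted p = 0.0783 and 0.0402 with an estimated correlation, so that the call for MyoD sites was lost. Camera sets the sites against all other tested regions, and the 2 sets make up most of the 11689. Each was thus tested mostly against the other, and the 2 p-values are not separate evidence. With fry the adjusted p was 0.153 and 0.0591.

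Around PU.1 sites the reads at the centre exceeded those of the flanks 5.29-fold and 6.02-fold in the Smad3 libraries of pro-B cells and 3.56-fold in IgG of pro-B cells, against 1.48-fold and 1.84-fold for Smad3 and 1.51-fold for IgG in myotubes. Around MyoD sites the ratio was 3.93 and 6.14 for Smad3 and 1.84 for IgG in myotubes, and 1.58 and 1.48 for Smad3 in pro-B cells. Relative to IgG of the same line, Smad3 over all PU.1 sites stood at 1.205 and 1.177 times IgG in pro-B cells and at 0.942 and 1.47 times in myotubes. The pro-B values lie between those of the myotube libraries, so the small summed difference at PU.1 sites averages unlike libraries. Over all MyoD sites Smad3 in myotubes stood at 1.66 and 3.61 times IgG. At the 83 Smad3 regions of pro-B cells with PU.1, Smad3 of pro-B cells stood at 4.16 and 5.70 times IgG, an excess that region calling itself required. At 285 PU.1 sites without an IgG read in either line, Smad3 reads of pro-B cells were 4.24 and 3.94 times the level of background bins, against 1.46 and 1.55 in myotubes. These sites were chosen for the absence of IgG reads, so Smad3 cannot be set against IgG there. They were also weaker than the full set of 7074 PU.1 sites, where the pro-B values were 9.19 and 8.98. Each line has 1 IgG library, and the intervals cover the spread over sites, not between libraries.

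**Figure D2:**
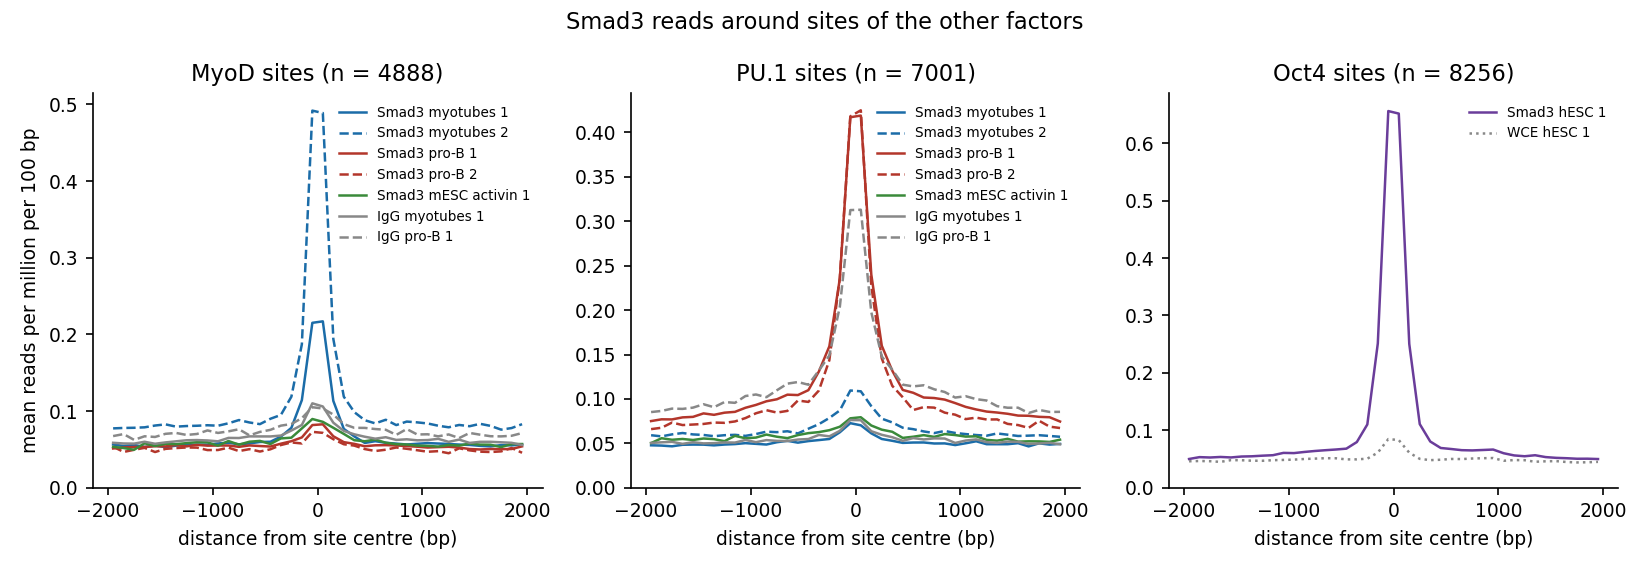
Mean RPM per 100 bp (vertical axis) against distance in bp from the site centre, for 4888 MyoD, 7001 PU.1 and 8256 Oct4 sites; each line is a library, coloured by cell type, with IgG and WCE in grey. At PU.1 sites the IgG library of pro-B cells (dashed grey) peaks with Smad3 of pro-B cells, with a ratio of centre to flank of 3.56.

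**Figure D3:**
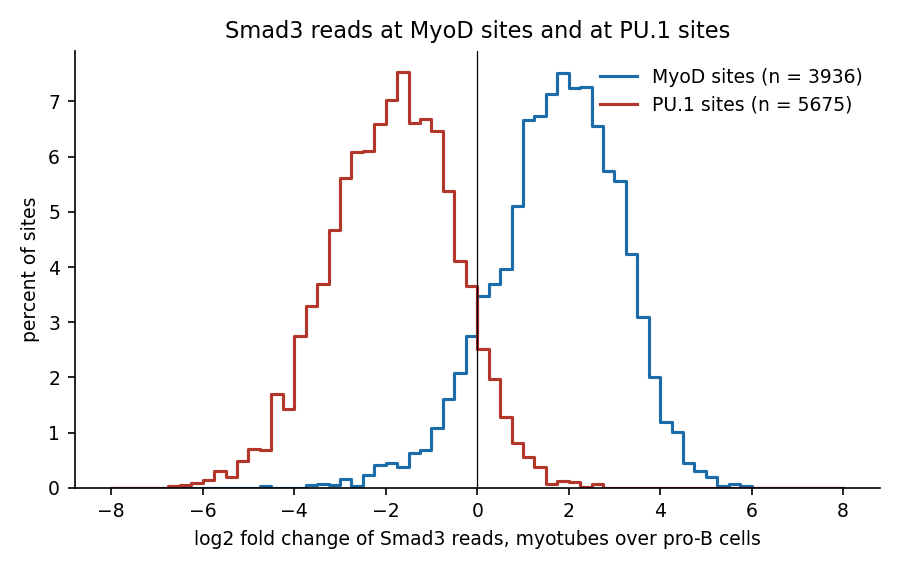
Percent of sites (vertical axis) by log2 fold change of Smad3 reads, myotubes over pro-B cells (horizontal axis), at 3936 MyoD sites and 5675 PU.1 sites. The medians are 1.85 and -1.82; IgG is not subtracted.

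The next question was how far Smad3 regions are specific to a cell type. With the control in the background few were shared: 4 of 64 myotube regions overlapped a Smad3 region of activin-treated V6.5 cells (6.25%, 2.46 to 14.998%), 5 of 145 pro-B regions did so (3.45%, 1.48 to 7.82%), and 4 of 64 myotube regions overlapped a pro-B region. Each share exceeded that of shifted regions (adjusted permutation p = 0.001, the smallest the shifts can give). Without regions within 10 kb of an IgG or WCE window, the myotube and V6.5 sets shared 0 of 59 regions (Wilson upper bound 6.11%). The myotube and pro-B sets then shared 1 of 59 and the pro-B and V6.5 sets 2 of 140 (1.43%), each still above shifted regions (adjusted permutation p = 0.00749). With a library left out the shares ranged from 1.61 to 9.55% for myotubes with V6.5 cells, 0.875 to 6.64% for pro-B with V6.5 cells and 0.576 to 9.38% for myotubes with pro-B cells. Without the control in the background the shares were 27.5% for myotubes with V6.5 cells (41 of 149), 11.2% for pro-B with V6.5 cells (45 of 402) and 29.5% for myotubes with pro-B cells (44 of 149).

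The Smad3 library of activin-treated V6.5 cells differed from those of the other cell types at many of 11689 tested regions. Against myotubes, 1970 regions were higher in the V6.5 library and 20 in myotubes. Against pro-B cells, 1975 were higher in the V6.5 library and 261 in pro-B cells. With 1 V6.5 library after activin, the spread behind these calls comes from the other groups, and cell type cannot be told apart from that library. The counts in the opposite directions are not comparable. The tested set held 1965 Smad3 regions of V6.5 cells, against 64 of myotubes and 145 of pro-B cells, which had to be called in both libraries. At these 64 and 145 regions the median log2 fold changes, V6.5 over the other cell type, were -3.22 and -3.74. Where the shallow V6.5 library held 0 reads the error was wide (SE 1.73 at chromosome 8 126781301–126782450). Of the 1965 tested Smad3 regions of V6.5 cells, 1906 were higher than in myotubes (median log2 fold change 5.15) and 1902 higher than in pro-B cells (5.23). These regions had been called in the same V6.5 library, so their direction is not independent evidence. The strongest was chromosome 1 182725201–182725900 (mm8), with 92.8 RPM in V6.5 cells after activin and 57.1 without, against 0.383 and 0.505 in myotubes and 0.323 and 0.459 in pro-B cells. Its log2 fold change was 7.50 ± 0.96 (SE) over myotubes (adjusted p = 9.36e-11, limma voom) and 7.71 ± 1.03 over pro-B cells (adjusted p = 7.17e-10). A neighbouring region, chromosome 1 182761251–182761850, held 69.99 RPM in V6.5 cells after activin, and its log2 fold change was 6.73 ± 0.96 over myotubes (adjusted p = 1.11e-08). The other regions higher than in myotubes were chromosome 2 154119251–154119800 (85 reads against 0 and 6), chromosome 12 87390651–87391250 (118 against 4 and 1) and chromosome 10 44080101–44080800 (109 against 2 and 2). Those higher than in pro-B cells were chromosome 9 110791951–110792600 (101 reads against 0 and 1), chromosome 16 84651651–84652200 (100 against 0 and 1), chromosome 14 54039801–54040500 (77 against 0 and 1) and the neighbouring region on chromosome 1 (190 against 3 and 0). Higher in myotubes, with 0 reads in V6.5 cells after activin, were chromosome 8 126781301–126782450 (30 and 51 reads, adjusted p = 0.0244), chromosome 11 59128251–59129050 (24 and 61), chromosome 8 97880401–97881550 (31 and 43), chromosome 8 94790651–94791050 (39 and 33) and chromosome 4 47519051–47519550 (35 and 37). Higher in pro-B than in V6.5 cells were chromosome 6 120533001–120533550 (189 and 50 reads against 2, adjusted p = 0.000912), chromosome 2 148254751–148255300 (127 and 58 against 1), chromosome 8 97936051–97936600 (203 and 34 against 0), chromosome 17 26986101–26987050 (166 and 36 against 1) and chromosome 15 81854901–81855500 (182 and 31 against 1). Leaving out the first pro-B library reduced the 1975 and 261 to 162 and 18. With a myotube library left out the 20 became 203 or 8.

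Between myotubes and pro-B cells, 771 regions were higher in myotubes and 1610 in pro-B cells. The 11689 tested regions were those called for Smad3, MyoD or PU.1, so called regions could hardly lie elsewhere. MyoD regions made up 4021 of them and held 755 of the 771, and PU.1 regions made up 5760 and held 1538 of the 1610. At the 771 regions the log2 ratio of summed reads was 4.07 for Smad3 and 0.60 for IgG. At the 1610 regions, myotubes over pro-B cells, it was -3.57 for Smad3 and -2.49 for IgG, a difference of -1.08 (-1.16 to -1.0). Both sets were chosen for their Smad3 reads in these libraries, so an excess of the Smad3 ratio over that of IgG is built in. Chromosome 8 87618501–87619050 (mm8), in a MyoD region, held 35 and 46 Smad3 reads in the myotube libraries and 0 and 2 in the pro-B libraries (adjusted p = 3.14e-05, limma voom). Chromosome 2 173056901–173057350, outside MyoD regions, held 41 and 54 against 0 and 0 (adjusted p = 0.000111), and chromosome 2 172906501–172906850, also outside, 30 and 44 against 0 and 2. In MyoD regions, chromosome 3 144580901–144581400 held 33 and 28 against 0 and 1, and chromosome 2 172950051–172950850 held 23 and 37 against 0 and 1. Chromosome 15 9436451–9437250, in a PU.1 region, held 9.15 and 24.8 RPM in pro-B cells against 0.255 and 0.336 in myotubes, a log2 fold change of -5.25 ± 0.90 (SE, adjusted p = 9.35e-06). Chromosome 10 118379201–118379600, outside PU.1 regions, held 7.97 and 13.8 RPM in pro-B cells and 0 and 4 reads in myotubes (adjusted p = 9.35e-06). In PU.1 regions, chromosome 2 148254751–148255300 held 127 and 58 reads in pro-B cells against 2 and 0 in myotubes, chromosome 15 36695651–36696250 held 153 and 21 against 0 and 2, and chromosome 15 63466101–63466700 held 84 and 48 against 2 and 1.

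The counts between myotubes and pro-B cells depend on the model and on single libraries. With limma trend, which differs from voom in prior count, weights and spread estimate, 0 regions passed in either direction (3810 at an unadjusted p under 0.05, against 4306 with voom). Without the first pro-B library 0 were higher in myotubes and 251 in pro-B cells by voom (1151 at an unadjusted p under 0.05). They were 205 and 785 without the second pro-B library, and 1701 and 1030 without the first myotube library. TMM over the regions themselves gave 1944 and 1338, so that 59.2% rather than 32.4% of called regions were higher in myotubes, and moved the median of all regions from -0.42 to 0.06.

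In BG03 cells Smad3 and Oct4 lay together at most Smad3 regions, and 29.5% of the 8304 Oct4 regions overlapped a Smad3 region. Smad3 reads at the centre of Oct4 sites were 12.6 times those of the flanks, against 1.83 for WCE. Of the 5 Smad3 regions with the most reads, 3 overlapped an Oct4 region. Chromosome 7 130940051–130941150 (hg18) held 22.2 Smad3 RPM (exact Poisson interval 19.01 to 25.7), 19.7 of Oct4 and 0.847 of WCE. The strongest, chromosome 19 4279201–4279850, held 41.9 of Smad3 (37.5 to 46.7), 1.52 of Oct4 and 1.57 of WCE, and overlapped no Oct4 region. Chromosome 3 57139701–57140350 held 183 Smad3, 92 Oct4 and 15 WCE reads, chromosome 8 128891351–128892050 held 161, 99 and 10, and chromosome 15 61127251–61128200, outside Oct4 regions, held 176, 54 and 15.

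The activin comparison asked what a short stimulation adds in V6.5 cells. Smad3 already occupied 1561 regions without added activin, 982 of which overlapped the 1967 regions after activin (62.9%, 60.5 to 65.3%). Smad2/3 occupied 617 regions, 442 of them overlapping Smad3 after activin (71.6%, 68.0 to 75.1%). Over 2662 regions of any of the 3 libraries the median log2 ratio of Smad3 reads, activin over untreated, was 0.34 (95% interval of the median 0.31 to 0.38), against 0.01 in background bins. It was 0.20 at the 982 regions of both libraries and 0.31 at Smad2/3 regions. At 1891 Smad3 regions of tetMyod1 cells on day 2 without Myod1, called independently of the V6.5 libraries, it was 0.15 (0.12 to 0.20). These tetMyod1 cells had also received activin, so this set may lean towards sites bound after activin. The same holds for the Smad2/3 regions, called after activin on the flow cell of the activin Smad3 library. It also holds for the 2662 regions, which pool both activin libraries with the untreated library. The choice of regions set the sign, at -0.18 for regions called without activin and 0.57 for regions called with it. The region on chromosome 1 182725201–182725900 went from 57.1 (48.7 to 66.6) to 92.8 (81.7 to 105) RPM, with 129 for Smad2/3. Chromosome 12 87390651–87391250 held 46.0 (38.5 to 54.5) without activin and 43.5 (35.98 to 52.1) with it, a difference not detectable at this depth. The neighbouring region on chromosome 1 held 152 reads without and 190 with activin, chromosome 17 70733051–70733900 held 85 and 114, and chromosome 10 44080101–44080800 held 74 and 109. The labels name another flow cell for the untreated library than for the activin libraries, so batch and activin cannot be told apart.

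The tetMyod1 libraries asked whether MyoD made in ESC changes where Smad3 lies. With Myod1 induced, Smad3 regions numbered 7163 on day 5 against 742 without, and 5375 on day 2 against 1891. Day 2 cells had received activin, and the labels name no activin for day 5. MyoD, precipitated through its Flag tag on day 5, occupied 1323 regions, of which 477 overlapped Smad3 with Myod1 on day 5 (36.1%, 33.5 to 38.7%) and 45 without (3.40%, 2.55 to 4.52%). On day 2 these shares were 19.05% and 7.26%. The reverse share, of Smad3 regions that lay on MyoD-Flag, was 6.62% with and 6.06% without Myod1 on day 5, and 4.69% and 5.08% on day 2. At MyoD-Flag regions the median log2 ratio, plus over no Myod1, was 1.86 (1.75 to 1.91) on day 5 and 0.74 (0.68 to 0.80) on day 2. Both medians were lower with a larger pseudocount, as given below.

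Most gained regions lay away from MyoD-Flag. Of 6625 regions found with Myod1 and not without on day 5, 437 overlapped MyoD-Flag (6.60%), and 2195 overlapped a Smad3 region of day 2 with Myod1 (33.1%). At Smad3 regions without a MyoD-Flag region the median was 2.08 on day 5 and 1.09 on day 2, though these regions were called in the libraries compared. At Smad3 regions of V6.5 cells it was 0.54 and 0.71, at MyoD regions of myotubes 1.08 and 0.41, and at PU.1 regions of pro-B cells 0.69 and 0.12, with 0 in background bins. A pseudocount of 5 lowered the medians on day 5 and day 2 to 0.47 and 0.22 at MyoD regions of myotubes and to 0.23 and 0.098 at PU.1 regions. Against random lists matched on read number, the MyoD-Flag median on day 5 (1.82 over 1320 regions) lay at percentile 100 (mean of random lists 1.30), and that on day 2 (0.71) at percentile 0.01 (0.83). The lists came from a pool of 9552 regions, which holds regions called in the Smad3 libraries compared, on either day. The percentiles therefore also reflect the choice of pool. Smad3 regions without MyoD-Flag had the higher median on day 5, at 2.08 against 1.86. The strongest region of day 5, chromosome 11 3092901–3093650 (mm8), held 44.8 RPM with Myod1, 17.3 without and 35.7 of MyoD-Flag. Chromosome 11 97477701–97478850, without a MyoD-Flag region, held 32.5 with Myod1, 7.33 without and 3.56 of MyoD-Flag. Chromosome 1 182725151–182725950 held 26.7 (23.5 to 30.2) with Myod1 and 31.8 (27.6 to 36.4) without. The other regions of day 5 were chromosome 7 132953151–132953850 (303 reads with and 41 without Myod1) and chromosome 4 140563501–140564200 (270 and 48). On day 2 the 5 strongest were chromosome 1 182725151–182726100 (829 and 534), chromosome 1 182761201–182761950 (500 and 363), chromosome 9 110791951–110793150 (384 and 299), chromosome 11 3093001–3093650 (375 and 329) and chromosome 10 44080051–44080900 (363 and 205). The strongest MyoD-Flag region, chromosome 4 139530951–139531500 (354 reads), held few Smad3 reads on day 5, 23 with and 10 without Myod1. Chromosome 9 60926001–60926550 (345 MyoD-Flag reads) held 53 and 1, chromosome 2 167714601–167715500 (266) held 18 and 1, and chromosome 9 108424951–108425600 (258) held 135 and 15.

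With both days in a fit, 602 of 10657 regions were higher with Myod1 and 0 lower (limma voom, 3848 at an unadjusted p under 0.05). Limma trend gave 569 and 0. The regions had been called in the same Smad3 libraries or in MyoD-Flag. Of them 7159 were regions of day 5 with Myod1, so the direction is not independent evidence. The region with the smallest adjusted p, chromosome 3 31285201–31286050, held 13.2 RPM with Myod1 and 3.53 without on day 2, and 17.4 and 1.37 on day 5, a log2 fold change of 2.56 ± 0.40 (SE, adjusted p = 1.61e-06). Chromosome 17 45065401–45065950, in MyoD-Flag and myotube MyoD regions, held 7.83 and 1.67 on day 2 and 16.1 and 3.82 on day 5 (2.25 ± 0.39, adjusted p = 4.39e-05). The others, all in MyoD-Flag regions, were chromosome 9 108424951–108425750 (2.25 ± 0.40), chromosome 14 24151051–24151650 (2.16 ± 0.42) and chromosome 2 167231301–167232250 (2.66 ± 0.52). The median of all regions was 1.30, and TMM over the regions, which removes it, left 0 regions in either direction (744 at an unadjusted p under 0.05). With regions from other libraries, a choice made after the data were seen, 8 of 6627 regions passed. That count became 141 with total reads as library size, 418 with limma trend and 174 with all deposited reads. It was 0 with TMM over the regions or without a filter. The day 5 libraries came from different flow cells, so batch and Myod1 cannot be told apart on that day.

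**Figure D4:**
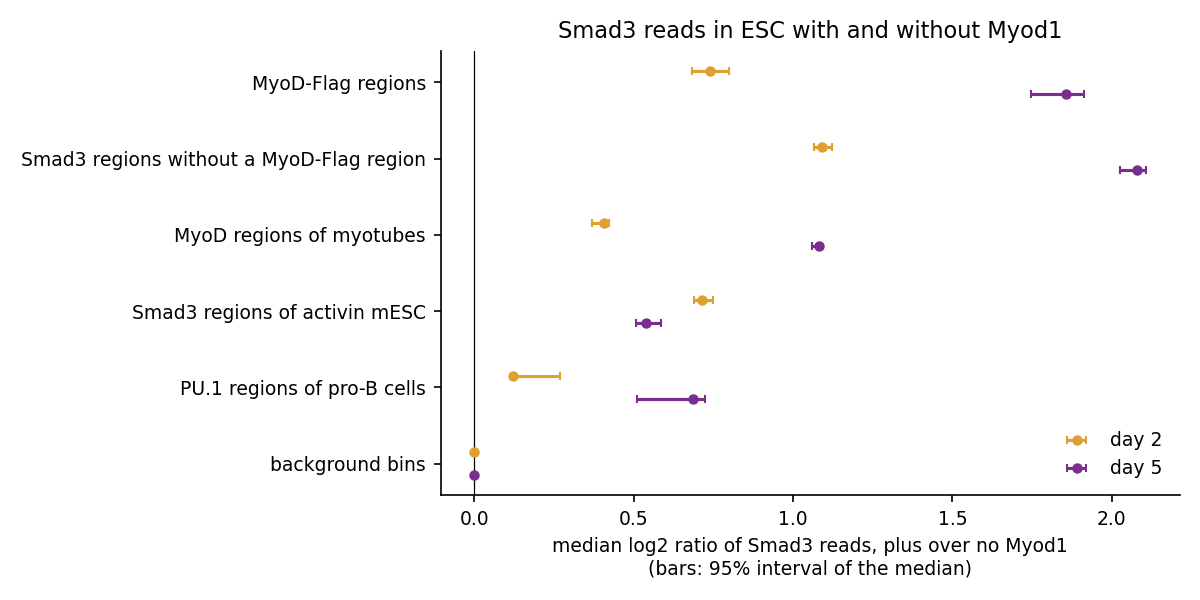
Median log2 ratio of Smad3 reads, plus over no Myod1 (horizontal axis), with its 95% interval, at 5 sets of regions and in background bins on day 2 and day 5. On day 5 the medians run from 0.54 at Smad3 regions of V6.5 cells to 2.08 at Smad3 regions without MyoD-Flag, with background bins at 0.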

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

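Both tests in this part were set before their own results were seen. Chromosome 8 took 6.79% ± 0.055 (SD, n = 3) of the background reads of the V6.5 libraries, against 5.37% ± 0.066 (SD, n = 5) in the tetMyod1 libraries, a difference between ESC lines in reads outside called regions, which also set the library sizes. Myotube libraries lay between these on chromosome 8 (5.99 to 6.17%), with a median segment ratio to tetMyod1 of 1.05. The ratio of V6.5 to tetMyod1 had a median of 1.28 over 5 Mb segments of chromosome 8, and 92.6% of them (25 of 27) lay above 1.1, which extra copies of the chromosome in part of the V6.5 cells may give, as a hypothesis. Shorter reads in the V6.5 libraries would move other chromosomes as well. Against all other mouse libraries, the autosome farthest from 1 apart from chromosome 8 was chromosome 15, 0.0971 away (ratio 0.903). Myotube libraries in that comparison were themselves raised on chromosome 15 (1.28 over tetMyod1), so the value does not measure read length. Against tetMyod1 alone the other autosomes ran from 0.962 to 1.02, which argues against read length as the account of the ratio on chromosome 8. All V6.5 libraries had the shorter seed, so line and read length did not vary separately.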

How the results depend on the processing

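Alternatives chosen after the data were seen were the removal of regions near IgG or WCE, Myod1 regions from other libraries, site sets with limma trend or without a filter, and subtraction of the IgG ratio. That subtraction took the summed Smad3 ratio at PU.1 sites from -1.96 to 0.019 (-0.031 to 0.066), and at MyoD sites from 1.80 to 1.95. The value at PU.1 sites averages unlike myotube libraries, at 0.942 and 1.47 times IgG, against 1.205 and 1.177 in pro-B cells. Its interval does not cover that spread. Regions higher in myotubes than in pro-B cells numbered 1944 with TMM over the regions and 0 with limma trend, and those higher in pro-B cells 0 with trend (3810 at an unadjusted p under 0.05) and 781 with all deposited reads. Regions higher in myotubes than in V6.5 cells went from 20 to 108 (TMM over regions), 136 (trend), 50 (no filter) and 0 (all deposited reads, limma voom, 2066 at an unadjusted p under 0.05), and those higher in pro-B than in V6.5 cells from 261 to 943 (trend), 402 (no filter) and 64 (all deposited reads). The 602 regions higher with Myod1 became 290 (total reads as library size), 0 (TMM over regions, 744 at an unadjusted p under 0.05) and 8 (regions from other libraries). With a library left out, regions higher in myotubes ranged from 0 to 1701 and in pro-B cells from 251 to 1996; in V6.5 cells over myotubes from 1900 to 2068 and the reverse from 8 to 203; in V6.5 over pro-B cells from 162 to 2101 and the reverse from 18 to 550. The adjusted p at MyoD sites ranged from 5.36e-112 to 6.11e-60 with a library left out and was 0.0783 with an estimated correlation and 0.153 with fry. At PU.1 sites it ranged from 5.54e-82 to 5.70e-51 and was 0.0591 with fry. With a library left out, overlap ranged from 43.3 to 85.9% for myotubes with MyoD, 39.8 to 84.1% for pro-B cells with PU.1, 1.56 to 6.25% for myotubes with PU.1, 3.37 to 10.3% for pro-B cells with MyoD, 1.61 to 9.55% for myotubes with V6.5 cells, 0.875 to 6.64% for pro-B with V6.5 cells and 0.576 to 9.38% for myotubes with pro-B cells. Thinning left 2 myotube regions and 0% overlap with MyoD, PU.1, V6.5 or pro-B regions, which follows from the fewer reads. Myotube overlap with PU.1 was 0% at 1e-12, 1.56% with midpoints within 200 bp and 1.69% without regions near IgG or WCE, which also took the overlap with V6.5 cells to 0%. The own-factor share stayed between 57.3 and 68.2% for BG03 cells. The activin median of 0.34 was 0.28 with a pseudocount of 5 and 0.40 with total reads. The day 2 median at MyoD-Flag regions was 0.81 and 0.47 with pseudocounts of 0.5 and 5, 0.67 with total reads and 0.84 with all deposited reads; away from them it was 0.92 with a pseudocount of 5, 1.02 with total reads, 1.15 with all deposited reads and 1.05 at 1e-12. On day 5 these were 2.14, 1.04, 1.70 and 2.09 at MyoD-Flag regions, and 2.18, 1.48, 1.93 and 2.22 away from them, for pseudocounts of 0.5 and 5, total reads and all deposited reads. For all of these the cause was not tested, except where named. Of the results for named regions, 75 kept their call and 15 lost it between myotubes and pro-B cells, against 83 and 7 (V6.5 with myotubes), 89 and 1 (V6.5 with pro-B cells) and 20 and 5 (Myod1). All deposited reads gave 171564 regions in the second Smad3 library of pro-B cells against 256, the library with 19.8% distinct reads. No paired analysis of replicates was possible because their numbers only name libraries, while the fit with Myod1 took the day as a covariate. DESeq2 was not run, because the plan replaced count tests by limma voom where the deposited files hold no counts, although reads were counted per region here.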

Other observations

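The tests chosen only after their result was seen were the overlap across flow cells, both comparisons with IgG, the thinned day 5 libraries and both tests of a higher enrichment of a whole library. Smad3 regions were shared between the ESC lines: 940 of 1891 regions of tetMyod1 cells on day 2 without Myod1 overlapped a Smad3 region of activin-treated V6.5 cells (49.7%, 95% Wilson interval 47.5 to 52.0%), and 510 of 742 did so on day 5 (68.7%, 65.3 to 72.0%). Of the 1323 MyoD-Flag regions of ESC, 256 overlapped a MyoD region of myotubes (19.4%, 17.3 to 21.6%). The myotube MyoD libraries shared 44.8% of the regions of the first and 65.6% of those of the second, so antibody and library are not separated from cell type. PU.1 and MyoD were largely apart, with 86 of 7160 PU.1 regions on a MyoD region (1.201%).

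Smad3 lay on regions of the factor of its cell type, and a biological link stays open. Carry-over between libraries of a flow cell would raise exactly shared read positions within it, and at MyoD regions their excess was 1.31 within and 1.203 between flow cells for the first myotube Smad3 library and 1.30 and 1.23 for the second (the lower ratio 1.06). In BG03 cells, where header and label name different flow cells for Oct4, the excess was 1.33 at Oct4 regions, while pairs of Smad3 and factor libraries from different flow cells reached 1.203 to 1.97, and 52.9% of regions of the first myotube Smad3 library overlapped MyoD of another flow cell. An enrichment shared with IgG does not account for the difference at MyoD sites, where Smad3 exceeded IgG by 1.95 (log2, myotubes over pro-B cells), but at PU.1 sites IgG showed a summed difference of the same size (-0.019, pro-B over myotubes, Smad3 minus IgG) and may account for it, provided that the pro-B IgG library, 1 per line, holds no PU.1 precipitate or wrong label, which was not tested. The sign of that summed difference also changes with the myotube library. Over PU.1 sites the myotube Smad3 libraries stood at 0.942 and 1.47 times IgG, on either side of 1.205 and 1.177 in pro-B cells. Other values leave a Smad3 share at PU.1 sites open: centre over flank was 5.29 and 6.02 for Smad3 against 3.56 for IgG, while the excess of 4.16 over IgG at pro-B Smad3 regions with PU.1 was required by the calling rule.

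Smad3 regions were more numerous with Myod1 on day 5. Thinned to equal depth the ratio of plus to no Myod1 was 7.19, against a difference in depth. The excess of positions shared with MyoD-Flag of the same flow cell was 1.347, or 0.99 of that on day 2 with Myod1 (1.361). In the libraries without Myod1, also of other flow cells, it was 1.502 on day 5 and 1.438 on day 2. The excess thus varied between libraries that share no flow cell with MyoD-Flag, so this ratio cannot decide on carry-over. The median at MyoD-Flag regions exceeded that at V6.5 Smad3 regions by 1.32 on day 5 but by 0.027 on day 2. With a pseudocount of 5 the medians were 1.04 and 0.41 on day 5, and 0.47 and 0.61 on day 2. Without Myod1 on day 5, Smad3 stood at 1.197 times IgG at MyoD-Flag regions and 4.01 times at V6.5 Smad3 regions. This IgG is the sum of the pro-B and myotube libraries, so these levels are relative to other cell lines. In reads alone, that Smad3 library held 6058 over the 1323 MyoD-Flag regions and 28023 over the 1967 V6.5 Smad3 regions. Sites that start at such different levels need not rise alike when the whole library is more enriched. The gap on day 5 therefore cannot tell a stronger precipitate from an effect of MyoD. A stronger precipitate stays a candidate explanation on both days. MyoD below the calling threshold at gained regions, where MyoD-Flag over the same summed IgG was 1.70 times that at regions without Myod1, cannot be told apart from open chromatin in these libraries. Flow cell and Myod1 remain confounded on day 5, and a biological effect of Myod1 stays among the open explanations.

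In the myotube libraries the median ratio to tetMyod1 ESC over 5 Mb segments was 1.28 on chromosome 15 and 0.808 on chromosome 7.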
